A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

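RNA from 15 budding yeast cultures was measured in 5 groups of 3 replicates, numbered 0, 1 and 2 in the labels. The groups were wild type (WT), ulp2, slx5, set1 and the ulp2 slx5 double mutant. Per the labels, cells grew in rich medium with glucose at 30 °C, and polyadenylated RNA was selected with oligo(dT). The series design text counts 3 mutants with 3 replicates each, and the labels list 4 mutant strains.

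The deposited table holds FPKM (fragments mapped to a transcript, scaled to its length and to the mapped total) for 7126 genes in each library. Per the submitters' processing notes, the authors used TopHat2 2.0.12 and Cuffdiff, whose version is not given, on genome build R64. Parameters, annotation, filters, library layout and strandedness were not stated. The columns had medians of 37.4 to 40.1 FPKM and sums of about 1213830 to 1761580 FPKM, so the values were not scaled to one table total. No further scaling was applied in the fit reported here. Of the 7126 genes, 6048 were matched by systematic name to the reference annotation, which gave their symbols and positions on R64, and 1078 were not matched. The unmatched genes took 5.60 to 7.40% of the FPKM of a library.

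Counts were not analysed here, so the depth of each library is unknown and no counting interval or detection limit was computed. A gene at 0 is described as listed at 0. Relative depth was estimated from genes with the lowest values, as the ratio at which most of them stood in WT replicate 1 and another library in whole-number steps. It ran from 0.470 for set1 replicate 0 to 1.05 for slx5 replicate 1. The genes at 0 numbered 645 to 819 per library, with the highest number in set1 replicate 0.

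Values were analysed as log2(FPKM + 1) for the 6474 genes with at least 1 FPKM in at least 3 of the 15 libraries. R 4.3.3 and limma 3.58.1 were used (lmFit, and eBayes with a trend). All 15 libraries entered a single fit with 10 residual degrees of freedom. The 7 differences tested were each of the 4 mutants against WT, the double mutant against ulp2 and against slx5, and the interaction of the ulp2 and slx5 deletions. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 3 replicates of a number were not treated as pairs, since no label links them and their deviations from the group means correlated by -0.128 to 0.140. A fit with the replicate number as a block was run as an alternative.

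Each of the 16 nuclear chromosomes got a score per library. The score is the median, over its tested genes, of the deviation of a gene from its mean over all libraries, less the same median over all other chromosomes. Of the tested genes, 5842 had a chromosome. The scores were compared by limma, with adjustment over 64 tests for the mutants against WT, over 32 between mutants, and over 16 for the interaction. An exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.1, which it gave for chromosomes I and XII in ulp2, VII in slx5, and I, XI and XIII in the double mutant against WT. Camera on the genes of each chromosome was added as a second test after the data were seen. In consecutive windows of about 30 genes, the median change of the genes was taken along each chromosome.

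Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of alternatives. The 32 lists included the SUMO pathway, COMPASS, MATa-specific, MATalpha-specific, haploid-specific, early meiosis, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, induced environmental stress response, chaperones, proteasome, sulfur assimilation and methionine, Gcn4 amino acid biosynthesis, phosphate regulon, iron regulon, ergosterol synthesis, respiratory chain and TCA cycle, glycolysis and fermentation, hexose transporters, DNA damage response, histones, cell wall, G1 and S phase, mitosis and G2, chromosome segregation, silent mating loci, PAU and COS families, subtelomeric genes within 30 kb of a chromosome end, Ty elements, and CLN3 with CCR4, which the published study tied to ulp2. Of these, 29 lists with at least 3 tested members went into camera with a preset correlation of 0.01, adjusted over 203 tests. Camera compares a list with all other genes. Each list was also tested with a correlation estimated from the data, and with fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes.

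The named genes are the deleted, marker and mating-type genes, and per comparison the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 FPKM in a group and no overlap between the groups, a condition not set for the interaction. Where the score of chromosome I or XII was called, these were taken outside both chromosomes, and the 5 called genes with the highest WT level on each of the 2 were named. In all 7 comparisons the rule was applied in that form. Up to 4 called members with the largest change per called list, and CLN3 and CCR4, were named too.

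The pipeline was tested on simulated data. Among 200 changed genes, 92% of those changed by 1 on the log2 scale and 98% of those changed by 2 were recovered, with 9 false calls among 199. A simulated unchanged group gave 0 calls at the adjusted threshold by limma. A shift of 0.5 put on chromosome VII was recovered as 0.49. It also led to 12 calls among the other 63 chromosome scores, none of them over 0.029 in size, so small scores were given little weight. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

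Alternatives changed the pseudocount (0.1 and 5), the filter (none, or at least 10 FPKM), the scaling (median ratio over all genes, median ratio outside chromosomes I and XII, quantile normalization), the block, the trend, a 2-fold limit, the genes entered, the groups fitted, the summary and centring of chromosome scores, and the correlation of the lists. Each library was left out in turn. Alternatives added after the data were seen left out chromosomes I, VII, XI, XII and XIII together, kept protein-coding genes alone, or took slx5 and set1 as the reference for ulp2. No library was excluded.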

Results

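Polyadenylated RNA was measured in 15 cultures of budding yeast, 3 replicates each of wild type (WT), ulp2, slx5, set1 and the ulp2 slx5 double mutant. ULP2 encodes a SUMO protease, SLX5 a subunit of a SUMO-targeted ubiquitin ligase, and SET1 the histone methyltransferase of COMPASS. The 7126 genes of the table summed to about 1213830 to 1761580 FPKM per library, and 645 to 819 of them were at 0. Counts were not analysed here, so the depth of each library is unknown. The ribosomal protein genes RPL41A and RPL41B together took 3.09 to 21.7% of the FPKM of a library. Across genes, which are not independent replicates, libraries of a group correlated by 0.960 to 0.981 and libraries of different groups by 0.923 to 0.960. Values in the text are mean FPKM ± SD with n = 3 libraries per group, and fold changes are log2, unless stated. For a gene list, members neither higher nor lower did not pass the test, and counts adjusted over the list alone are given where they differed from those over all genes.

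The first check asked whether each library carried the genotype of its label. ULP2 (YIL031W, chromosome IX, 292633 to 295737 on build R64) stood at 30.4 ± 1.88 in WT, and at means of 0.0356 in ulp2 and 0.0152 in the double mutant. For SLX5 (YDL013W, chromosome IV, 429067 to 430926), WT had 29.4 ± 3.58, slx5 a mean of 0.0395 and the double mutant 0.0255. SET1 (YHR119W, chromosome VIII, 346043 to 349285) stood at 27.9 ± 3.37 in WT and at a mean of 0.104 in set1. Each of the 3 genes had a mean of at least 25.1 in the groups whose labels keep it. LEU2 and URA3, auxotrophic markers, were listed at 0 in all libraries, and HIS3, given as a his3 allele in the WT label, had a mean of 94.9 in WT and 150 in set1.

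Mating-type genes and other markers departed from the labels, which give MATa for WT and MATalpha with a MET15 (MET17) deletion for every mutant. HMRA1 (YCR097W, chromosome III, 293835 to 294321), whose sequence is shared with the MATa1 gene, had 234 ± 33.8 in WT and 211 ± 8.03 in the double mutant. In ulp2 it reached at most 0.206% of its WT level in a library, and it was listed at 0 in slx5 and set1. The alpha-factor gene MF(ALPHA)1 had 5.73 ± 2.89 in WT and 8.78 ± 3.33 in the double mutant, against 3967 ± 286 in ulp2, 4426 ± 48.8 in slx5 and 3524 ± 218 in set1. LYS2, a lysine synthesis gene deleted in the WT label, stood at means of 0.0398 in WT and 0.0694 in set1. In the other mutants LYS2 had 46.2 ± 1.60 (ulp2), 43.4 ± 0.624 (slx5) and 37.0 ± 2.01 (double mutant). MET17, the sulfhydrylase deleted as met15 in the mutant labels, had 137 ± 16.4 in WT, 310.2 ± 22.1 in ulp2, 300.3 ± 16.9 in set1 and 228 ± 5.35 in the double mutant, and 0.726 ± 0.350 in slx5. Hence ulp2, slx5 and set1 differed from WT in mating-type expression as well as in the named deletion, and the double mutant differed from ulp2 and slx5 in it. LYS2 also set ulp2, slx5 and the double mutant apart from WT, and MET17 slx5 from all others.

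**Figure D1:**
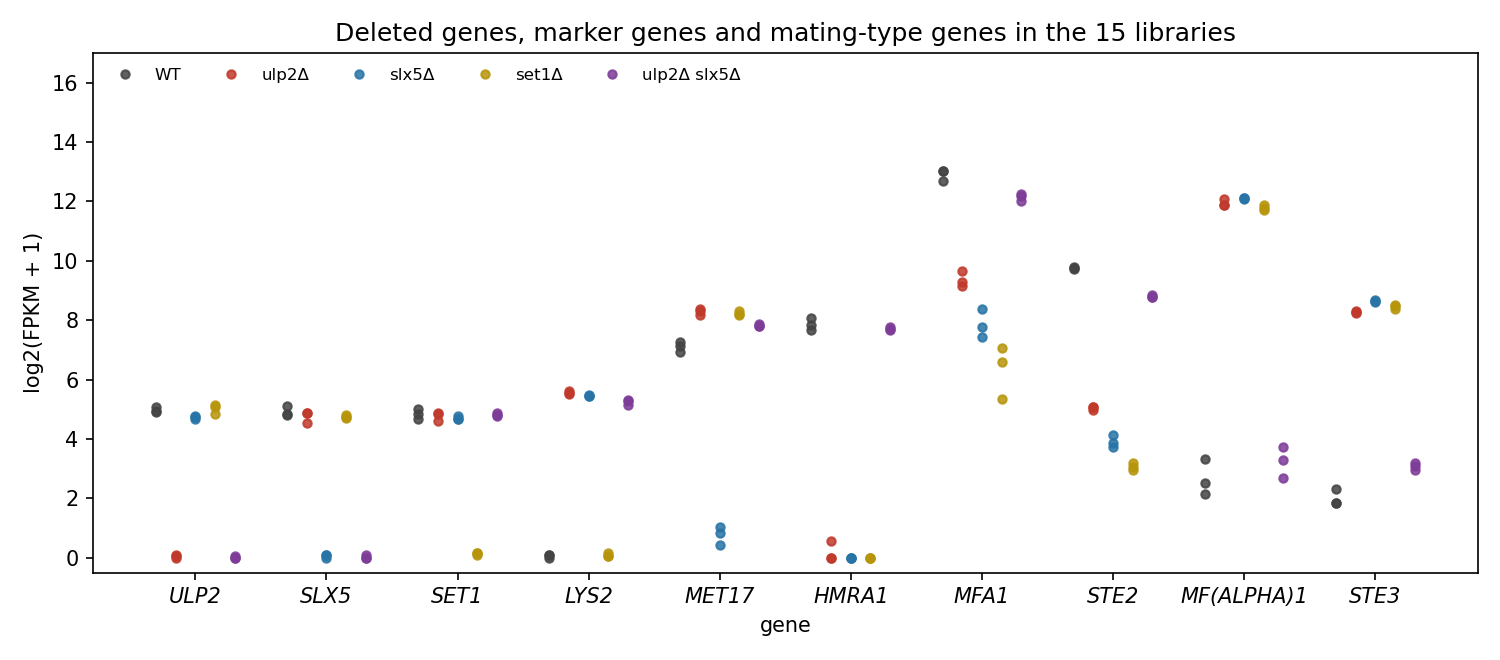
Level of the deleted genes, the marker genes and mating-type genes as log2(FPKM + 1) on the y axis, with a point for each of the 15 libraries by group. HMRA1 has means of 234 FPKM in WT and 211 FPKM in the double mutant and lies near 0 in the other 3 groups.

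Chromosomes I and XII were singled out before the data were examined. They were chosen because the published study concerns them, so their rise in ulp2 is not independent evidence. In ulp2, genes of chromosomes I and XII rose together. The median gene of chromosome I was higher by 0.95 (95% confidence interval 0.92 to 0.98) than genes elsewhere, and that of chromosome XII by 0.81 (0.79 to 0.82). Of 91 tested genes on chromosome I, 88 were higher and 0 lower, and of 494 on chromosome XII, 456 were higher and 0 lower. Among the most abundant of them, the elongation factor gene EFB1 (YAL003W) went from 4049 ± 269.9 to 6513 ± 258 and the pyruvate kinase gene CDC19 (YAL038W) from 2713 ± 72.4 to 3549 ± 97.0. The cysteine synthesis gene CYS3 (YAL012W) went from 373 ± 46.7 to 848 ± 44.6, and the pyruvate decarboxylase gene PDC1 (YLR044C) on chromosome XII from 7017 ± 435 to 8852 ± 361. CLN3 (YAL040C, chromosome I, 65778 to 67520), a G1 cyclin gene fixed in advance, rose by 1.14. CCR4 (YAL021C, chromosome I, 110846 to 113359), a deadenylase gene fixed with it, rose by 0.65, and the standard errors of both were 0.086 to 0.087. The published study had tied this pair to ulp2, so it is not independent evidence.

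The rise spanned both chromosomes, with medians of 0.83 to 1.14 over the 3 windows of about 30 genes on chromosome I and of 0.77 to 0.91 over the 16 windows on chromosome XII. By limma on the chromosome scores the adjusted p was 3.06e-19 for chromosome I and 4.13e-22 for chromosome XII, and each of the 3 ulp2 libraries lay above each WT library. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The other 14 chromosomes differed by -0.12 to 0.073. Of these, 11 passed the limma test on scores, while camera on their genes called chromosome IV alone.

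**Figure D2:**
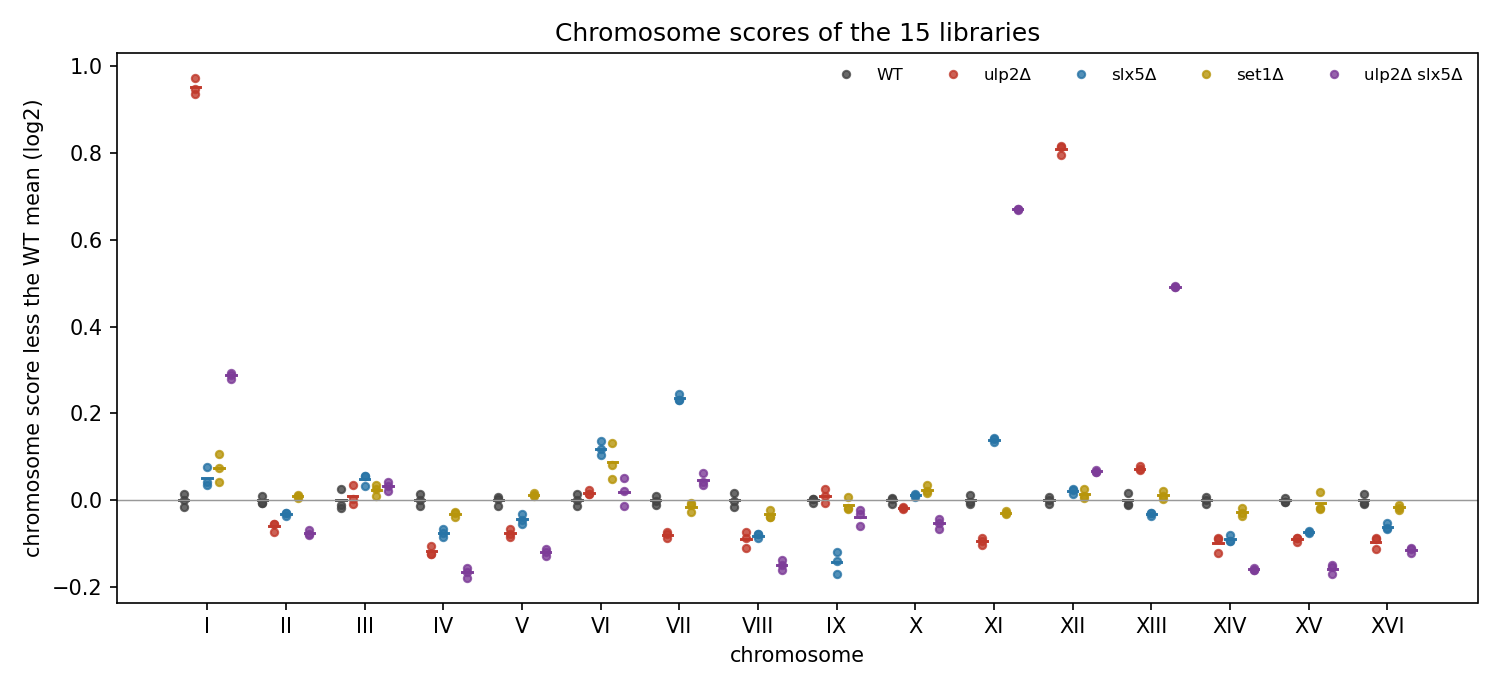
Chromosome score of each of the 15 libraries less the WT mean (y axis, log2) by chromosome (x axis). Chromosomes I and XII stand apart in ulp2 by 0.95 and 0.81, VII in slx5 by 0.24, and I, XI and XIII in the double mutant by 0.29, 0.67 and 0.49.

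**Figure D3:**
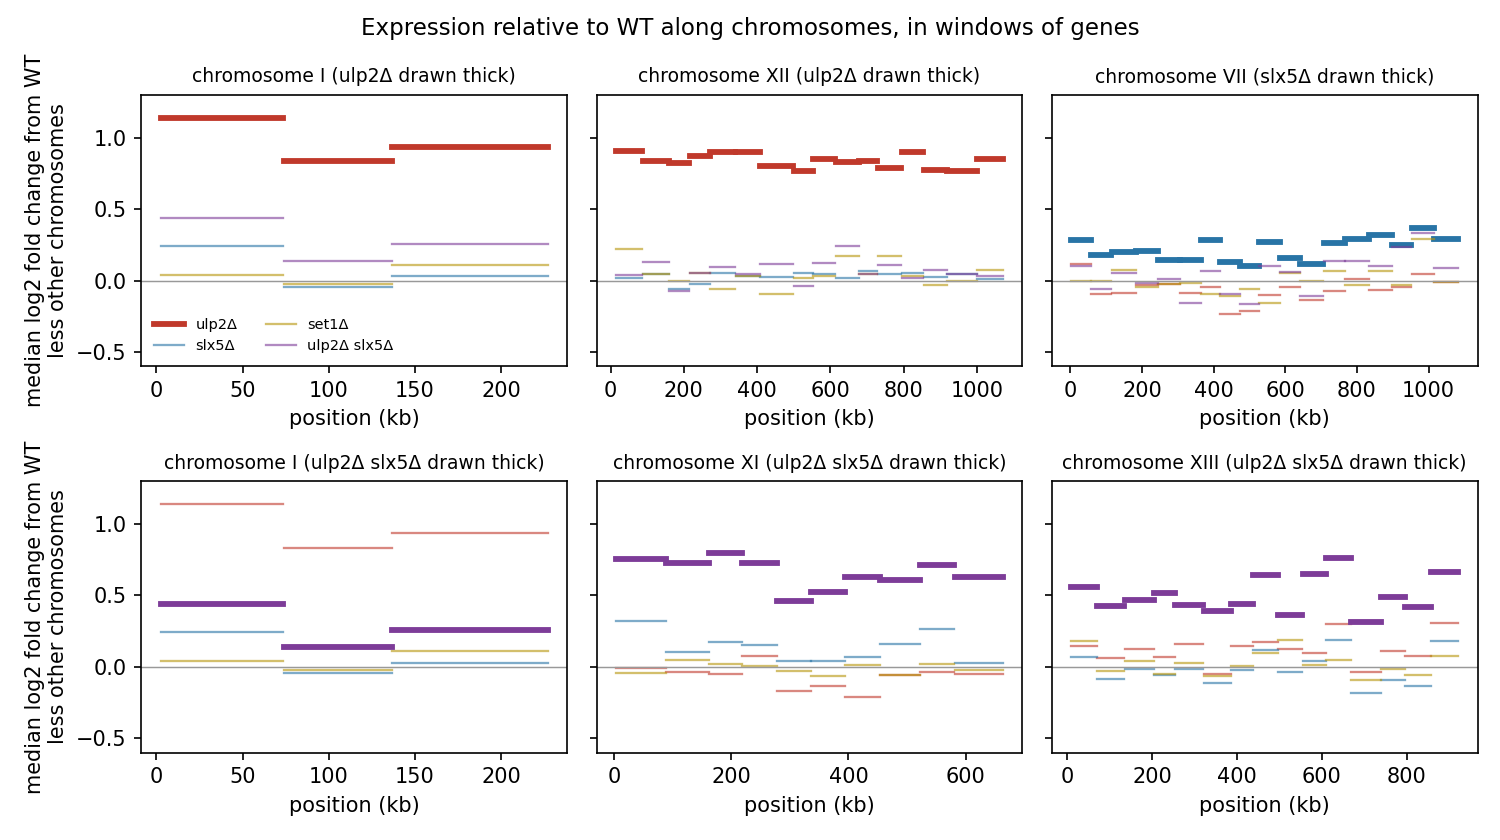
Median log2 fold change from WT in windows of about 30 genes, less that of the other chromosomes (y axis), along the position in kb (x axis), with the mutant of interest drawn thick. In ulp2 all 16 windows of chromosome XII lie between 0.77 and 0.91.

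Beyond these chromosomes, ulp2 had higher stress, meiotic and subtelomeric transcripts and lower ribosomal protein transcripts, a comparison addressing ULP2 loss. These list calls were lost with an estimated correlation, at adjusted p = 0.137 for stress, 0.0586 for early meiosis and for subtelomeric genes, and 0.0993 and 0.576 for mitochondrial and cytosolic ribosomal proteins. Of 6474 tested genes, 1799 were higher and 1727 lower. By at least 2-fold, 494 were higher, 156 of them on chromosomes I and XII, and 49 lower. Apart from the deleted, marker and mating-type genes and from chromosomes I and XII, the stress gene HSP12 (YFL014W, chromosome VI) rose by 4.97, from 11.1 ± 2.86 to 371 ± 11.8. The cell wall gene PIR3 (YKL163W) rose by 4.23, the small heat shock gene HSP26 (YBR072W) by 3.82 and FIG1 (YBR040W), known as induced by pheromone, by 3.53. Among the same genes, the cell wall mannoprotein gene TIR1 (YER011W, chromosome V, -2.42) fell from 662 ± 43.6 to 123 ± 6.35. The ribosomal protein gene RPL8A (YHL033C, -2.33) and the zinc transporter gene ZRT1 (YGL255W, -1.98) fell. These 7 genes had standard errors of 0.054 to 0.15. Against slx5 and set1, which like ulp2 expressed MF(ALPHA)1, 3031 genes were called, a choice made after seeing the data. Of 3526 calls against WT, 1966 recurred there in the same direction.

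Induced genes of the environmental stress response rose as a group (26 higher and 2 lower of 30, median 1.42, adjusted p = 5.04e-10, adjusted p = 0.137 with an estimated correlation). Mating-type genes followed the expression given above, with the MATalpha-specific list higher (4 higher and 0 lower of 4, median 6.23, adjusted p = 2.80e-06, adjusted p = 0.0104 with an estimated correlation). The MATa-specific list, which also holds AFB1, a gene of alpha cells, was lower (1 higher and 7 lower of 8, median -3.29, adjusted p = 0.000118, adjusted p = 0.0954 with an estimated correlation). Targets of Gcn4 in amino acid biosynthesis rose (24 higher and 1 lower of 37, median 0.36, adjusted p = 1.09e-05, adjusted p = 0.179 with an estimated correlation). The arginine synthesis gene ARG3 changed by 1.87 and ARG1 by 1.56. Early meiosis genes rose (13 higher and 1 lower of 16, median 0.81, adjusted p = 0.000163, adjusted p = 0.0586 with an estimated correlation). The cohesin gene REC8 changed by 1.97, the axis gene RED1 by 1.46 and the recombination nuclease gene SPO11 by 1.2. Genes of sulfur assimilation and methionine rose (17 higher and 3 lower of 24, 18 and 3 adjusted over the list alone, median 0.56, adjusted p = 0.000338, adjusted p = 0.0244 with an estimated correlation). The cystathionine lyase gene STR3 changed by 1.82. Subtelomeric genes were higher as a list (154 higher and 37 lower of 320, 156 and 38 adjusted over the list alone, median 0.41, adjusted p = 3.62e-05, adjusted p = 0.0586 with an estimated correlation). The PAU and COS families were higher (15 higher and 1 lower of 24, median 1.14, adjusted p = 0.00205, adjusted p = 0.0586 with an estimated correlation). PAU5 changed by 2.45 and PAU23 by 2.11.

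Cell wall genes rose in ulp2 (16 higher and 5 lower of 22, median 0.60, adjusted p = 0.00124, adjusted p = 0.254 with an estimated correlation). The mannoprotein gene CWP1 changed by 3.04. Hexose transporter genes rose (9 higher and 1 lower of 16, median 0.83, adjusted p = 0.00150, adjusted p = 0.103 with an estimated correlation). HXT9 changed by 1.74 and HXT4 by 1.17. The DNA damage response rose (9 higher and 2 lower of 15, median 0.55, adjusted p = 0.0250, adjusted p = 0.295 with an estimated correlation). The ribonucleotide reductase gene RNR3 changed by 1.49 and its regulator HUG1 by 1.42. Genes of mitochondrial ribosomal proteins fell (2 higher and 54 lower of 67, median -0.39, adjusted p = 2.26e-09, adjusted p = 0.0993 with an estimated correlation). MRPL19 changed by -0.67 and MRPL33 by -0.66. Genes of cytosolic ribosomal proteins fell too (10 higher and 67 lower of 137, median -0.33, adjusted p = 3.83e-07, adjusted p = 0.576 with an estimated correlation). RPL22B changed by -1.25, RPS9A by -1.0 and RPL37A, which lies on chromosome XII, by 0.89. The G1 and S phase list was lower (3 higher and 13 lower of 19, 3 and 14 adjusted over the list alone, median -0.35, adjusted p = 0.00597, adjusted p = 0.199 with an estimated correlation). The cyclin gene CLN1 changed by -0.99 and the cohesin gene MCD1 by -0.80. The phosphate regulon was lower (3 higher and 11 lower of 16, median -0.32, adjusted p = 0.00673, adjusted p = 0.247 with an estimated correlation). The acid phosphatase gene PHO12 changed by -1.26 and PHO5 by -1.17.

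The SUMO pathway, which includes the deleted ULP2, was lower (1 higher and 7 lower of 14, median -0.18, adjusted p = 0.0383, adjusted p = 0.278 with an estimated correlation). The list was not tested without ULP2. The SUMO ligase gene NFI1 changed by -0.55. The call was lost without WT replicate 1 (adjusted p = 0.0778) and without ulp2 replicate 0 (adjusted p = 0.0647). Its adjusted p over all alternatives was 1.24e-07 to 0.278. Quantile normalization ended the calls of early meiosis, cytosolic ribosomal proteins, hexose transporters, DNA damage response and subtelomeric genes. A filter of at least 10 FPKM ended those of the SUMO pathway and hexose transporters, and a pseudocount of 0.1 that of the SUMO pathway. Genes of COMPASS were not called (median -0.062, 3 higher and 0 lower of 8, adjusted p = 0.547, 2 and 0 adjusted over the list alone), and their mean of 0.15 differed in sign from the median. Ribosome biogenesis (median 0.00879, 24 higher and 14 lower of 72, adjusted p = 0.464), chaperones (median 0.059, 9 higher and 5 lower of 20, adjusted p = 0.191) and the iron regulon (median 0.13, 10 higher and 6 lower of 24, adjusted p = 0.451) were not called either.

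In slx5 cells, the lists for stress, respiration and the DNA damage response rose, and those for ribosomes and their production fell, in a comparison that addresses the loss of the SUMO-targeted ligase. With an estimated correlation, respiration kept its call (adjusted p = 0.0104). Stress and DNA damage (0.0586 each), cytosolic ribosomal proteins (0.363) and ribosome biogenesis (0.254) lost theirs. HSP12 went from 11.1 ± 2.86 to 847 ± 46.4 (6.16), and the stress gene DDR2 (YOL052C-A, chromosome XV) rose by 5.83. The hexokinase gene HXK1 (YFR053C) rose by 4.53 and HUG1 (YML058W-A), a regulator of ribonucleotide reductase, by 4.48. Falls included the anaerobic translation factor gene ANB1 (YJR047C, -2.39), TIR1 (-2.06), the mannoprotein gene FIT1 of iron uptake (YDR534C, -2.02) and the phosphatase gene PHO5 (YBR093C, -1.91). Standard errors for these genes were 0.054 to 0.22. Of 6474 genes, 1659 were higher and 1626 lower, of which 411 and 53 changed by at least 2-fold, and MATa-specific and MATalpha-specific genes differed from WT as in ulp2.

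Chromosome VII was higher in slx5 by 0.24 (0.22 to 0.26, adjusted p = 1.68e-13), with 246 genes higher and 39 lower of 531, and with window medians of 0.10 to 0.37. Chromosome XI was higher by 0.14, with 128 genes higher and 41 lower of 314, VI by 0.12, and IX was lower by -0.14. Camera on the genes called VII, IX and XI among the 15 chromosomes that passed the score test. Chromosome I differed by 0.052 and XII by 0.022. The call of chromosome I ended without WT replicate 0 (0.04) and without slx5 replicate 1 (0.028), and that of XII ended without WT replicate 0 (0.012). CLN3 and CCR4 did not pass the test in slx5, with log2 values of 0.06 and -0.18.

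All induced stress response genes were higher (30 higher and 0 lower of 30, median 2.0, adjusted p = 4.41e-19, adjusted p = 0.0586 with an estimated correlation). The respiratory chain and TCA cycle rose (44 higher and 0 lower of 45, median 0.93, adjusted p = 1.49e-17, adjusted p = 0.0104 with an estimated correlation). The cytochrome gene CYC7 changed by 2.57, the citrate synthase gene CIT1 by 1.8 and QCR9, a gene of complex III on chromosome VII, by 1.53. Chaperone genes rose (13 higher and 3 lower of 20, 15 and 3 adjusted over the list alone, median 0.56, adjusted p = 5.42e-05, adjusted p = 0.0877 with an estimated correlation). SSA1 changed by 2.94, HSP82 by 1.8 and HSP104 by 1.53. Proteasome genes rose (25 higher and 0 lower of 33, median 0.32, adjusted p = 9.44e-07, adjusted p = 0.260 with an estimated correlation). PUP2 changed by 0.64 and SCL1, which lies on chromosome VII, by 0.56. DNA damage response genes rose (11 higher and 0 lower of 15, 13 and 0 adjusted over the list alone, median 0.89, adjusted p = 9.90e-07, adjusted p = 0.0586 with an estimated correlation). RNR3 changed by 2.66 and the glycosylase gene MAG1 by 1.38. Cytosolic ribosomal protein genes fell (0 higher and 97 lower of 137, 0 and 99 adjusted over the list alone, median -0.48, adjusted p = 2.57e-15, adjusted p = 0.363 with an estimated correlation). RPS14B changed by -1.14 and RPL7B by -1.13. Ribosome biogenesis fell (2 higher and 53 lower of 72, 2 and 54 adjusted over the list alone, median -0.31, adjusted p = 5.85e-10, adjusted p = 0.254 with an estimated correlation). The snoRNP gene GAR1 changed by -0.96 and NOP56 by -0.84. Sulfur assimilation and methionine rose (19 higher and 1 lower of 24, median 0.41, adjusted p = 2.88e-05, adjusted p = 0.0104 with an estimated correlation). This rise was not separated from MET17 loss. STR3 changed by 1.64.

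Hexose transporters rose in slx5 (9 higher and 0 lower of 16, median 0.58, adjusted p = 0.000129, adjusted p = 0.0634 with an estimated correlation). HXT7 changed by 2.17. Subtelomeric genes rose as a list (128 higher and 36 lower of 320, 129 and 37 adjusted over the list alone, median 0.29, adjusted p = 0.000300, adjusted p = 0.0634 with an estimated correlation). PAU and COS genes were higher (12 higher and 0 lower of 24, median 0.50, adjusted p = 0.00326, adjusted p = 0.0634 with an estimated correlation). COS12 changed by 3.04. The cell wall list was higher (14 higher and 6 lower of 22, median 0.74, adjusted p = 0.00343, adjusted p = 0.295 with an estimated correlation). PIR3 changed by 3.87. Gcn4 targets rose (19 higher and 5 lower of 37, median 0.19, adjusted p = 0.00547, adjusted p = 0.375 with an estimated correlation). ARG3 changed by 1.91. Early meiosis was higher (10 higher and 1 lower of 16, median 0.43, adjusted p = 0.0218, adjusted p = 0.179 with an estimated correlation). REC8 changed by 1.44. MATalpha-specific genes were higher (4 higher and 0 lower of 4, median 6.60, adjusted p = 9.84e-07, adjusted p = 0.0104 with an estimated correlation). MATa-specific genes were lower (1 higher and 7 lower of 8, median -3.84, adjusted p = 1.11e-05, adjusted p = 0.0634 with an estimated correlation). Haploid-specific genes were not called (median 0.000697, 1 higher and 3 lower of 11, adjusted p = 0.427), and their mean of -0.15 differed in sign from the median.

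The phosphate regulon fell in slx5 (3 higher and 8 lower of 16, median -0.29, adjusted p = 0.0305, adjusted p = 0.349 with an estimated correlation). PHO12 changed by -1.67. Its call ended without WT replicate 0 (adjusted p = 0.0553). Over all alternatives the adjusted p was 1.12e-06 to 0.349. Leaving out chromosomes I and XII ended it too. Quantile normalization ended the calls of early meiosis, phosphate regulon and subtelomeric genes. A filter of at least 10 FPKM ended that of early meiosis, and leaving out chromosomes I, VII, XI, XII and XIII that of the cell wall.

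Cells without SET1, a mutant of chromatin rather than of the SUMO pathway, had no chromosome shift of the size seen in ulp2. Chromosome scores differed from WT by -0.032 to 0.088, with 0.075 for chromosome I (adjusted p = 0.000179), and camera called 0 of the 16 chromosomes. The score of chromosome XII was 0.014 and not called (adjusted p = 0.0941), though it was called without set1 replicate 2 (0.022). CLN3 and CCR4 did not pass the test, at 0.23 and -0.10. Of 6474 genes, 1430 were higher and 983 lower, and 223 and 37 of them changed by at least 2-fold, while a fit on set1 and WT alone called 1465. Rises outside the mating-type and marker genes included FIG1 (YBR040W, 3.01), HXK1 (2.90), HUG1 (2.74) and BNA2 (YJR078W, 2.55), which acts in NAD synthesis from tryptophan. Falls included the mannoprotein genes FIT3 (YOR383C, -1.88) and FIT2 (YOR382W, -1.41) of iron uptake, and GLC7 (YER133W, -1.07), the catalytic subunit of protein phosphatase 1. Standard errors over these 7 genes were 0.068 to 0.16.

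Induced stress response genes rose in set1 (27 higher and 0 lower of 30, 28 and 0 adjusted over the list alone, median 1.23, adjusted p = 2.57e-15, adjusted p = 0.0754 with an estimated correlation). Hexose transporters were higher (8 higher and 0 lower of 16, median 0.69, adjusted p = 1.71e-05, adjusted p = 0.0586 with an estimated correlation). HXT4 changed by 1.88. Genes of the respiratory chain and TCA cycle rose (24 higher and 0 lower of 45, median 0.26, adjusted p = 1.84e-05, adjusted p = 0.108 with an estimated correlation). CYC7 changed by 1.93 and CIT1 by 0.88. The cell wall list rose (13 higher and 2 lower of 22, median 0.36, adjusted p = 0.000922, adjusted p = 0.247 with an estimated correlation). CWP1 changed by 2.48. The proteasome list rose (13 higher and 1 lower of 33, 15 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.00312, adjusted p = 0.526 with an estimated correlation). Mitosis and G2 genes rose (9 higher and 0 lower of 14, median 0.22, adjusted p = 0.00570, adjusted p = 0.217 with an estimated correlation). The cytokinesis gene IQG1 changed by 0.55 and BUD4 by 0.45. The PAU and COS families rose (6 higher and 1 lower of 24, median 0.60, adjusted p = 0.0164, adjusted p = 0.103 with an estimated correlation). The DNA damage response was higher (8 higher and 1 lower of 15, median 0.41, adjusted p = 0.0194, adjusted p = 0.279 with an estimated correlation). RNR3 changed by 0.81 and RNR1 by -0.77.

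Mitochondrial ribosomal protein genes fell in set1 (2 higher and 22 lower of 67, median -0.15, adjusted p = 0.000230, adjusted p = 0.272 with an estimated correlation). MRPL25 changed by -0.61. The iron regulon fell (4 higher and 12 lower of 24, 4 and 13 adjusted over the list alone, median -0.18, adjusted p = 0.00299, adjusted p = 0.0571 with an estimated correlation). The siderophore transporter gene ARN2 changed by -0.88 and the mRNA decay gene TIS11 by -0.87. G1 and S phase genes fell (0 higher and 7 lower of 19, 2 and 8 adjusted over the list alone, median -0.11, adjusted p = 0.0132, adjusted p = 0.237 with an estimated correlation). MCD1 changed by -0.71 and CLN1 by -0.70. The MATalpha-specific list was higher (4 higher and 0 lower of 4, median 6.46, adjusted p = 7.44e-09, adjusted p = 0.00635 with an estimated correlation). The MATa-specific list was lower (1 higher and 7 lower of 8, median -5.39, adjusted p = 3.33e-09, adjusted p = 0.0293 with an estimated correlation). Leaving out chromosomes I, VII, XI, XII and XIII ended the call of the DNA damage response.

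Cytosolic ribosomal proteins were called lower in set1 (0 higher and 11 lower of 137, 0 and 5 adjusted over the list alone, median -0.023, adjusted p = 0.0185, adjusted p = 0.797 with an estimated correlation). RPS9A changed by -0.96 and RPS14B by -0.82. This call ended by fry and without WT replicate 0 (adjusted p = 0.879) and without set1 replicate 2 (adjusted p = 0.288). Over its alternatives, the adjusted p was 8.91e-07 to 0.879. COMPASS, which includes the deleted SET1, was lower (1 higher and 3 lower of 8, median -0.17, adjusted p = 0.0320, adjusted p = 0.121 with an estimated correlation). The subunit gene SHG1 changed by -0.40. Its call was lost without set1 replicate 0 (adjusted p = 0.0704). The alternatives gave an adjusted p of 1.85e-09 to 0.121. Haploid-specific genes were lower (1 higher and 4 lower of 11, median -0.14, adjusted p = 0.0353, adjusted p = 0.295 with an estimated correlation). The bud-site protease gene AXL1 changed by -0.60. That call was lost without WT replicate 1 (adjusted p = 0.0702) and without WT replicate 2 (adjusted p = 0.0522). Among all settings the adjusted p was 0.00164 to 0.295. Sulfur assimilation and methionine genes were higher (14 higher and 4 lower of 24, 15 and 4 adjusted over the list alone, median 0.25, adjusted p = 0.0365, adjusted p = 0.108 with an estimated correlation). STR3 changed by 0.82. This list was not called without set1 replicate 1 (adjusted p = 0.0677) and without set1 replicate 2 (adjusted p = 0.0522). In all settings the adjusted p was 1.62e-08 to 0.126. Early meiosis genes were higher (9 higher and 1 lower of 16, 9 and 2 adjusted over the list alone, median 0.45, adjusted p = 0.0457, adjusted p = 0.237 with an estimated correlation). REC8 changed by 1.21. They were not called without WT replicate 0 (adjusted p = 0.0731), without WT replicate 2 (adjusted p = 0.0588) and without set1 replicate 2 (adjusted p = 0.0581). Over all settings the adjusted p was 1.82e-05 to 0.579. Subtelomeric genes were higher (92 higher and 37 lower of 320, 96 and 43 adjusted over the list alone, median 0.19, adjusted p = 0.0473, adjusted p = 0.264 with an estimated correlation). They lost the call without WT replicate 1 (adjusted p = 0.105) and without set1 replicate 2 (adjusted p = 0.0739). All settings gave an adjusted p of 1.41e-05 to 0.410. Quantile normalization ended these 6 calls, and leaving out chromosomes I, VII, XI, XII and XIII those of haploid-specific genes, early meiosis, sulfur assimilation and subtelomeric genes. A filter of at least 10 FPKM ended those of haploid-specific genes, early meiosis and subtelomeric genes, a pseudocount of 5 those of early meiosis and subtelomeric genes, no filter that of subtelomeric genes, and leaving out I and XII those of sulfur assimilation and subtelomeric genes.

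In the ulp2 slx5 double mutant, chromosomes XI, XIII and I were higher, and chromosome XII was close to the rest. The comparison addresses the loss of both SUMO factors, and here both strains expressed HMRA1. Chromosome XI was higher by 0.67 (0.65 to 0.68, adjusted p = 7.58e-22), with 266 genes higher and 5 lower of 314. Chromosome XIII was higher by 0.49 (0.47 to 0.51, adjusted p = 3.85e-19), with 344 higher and 17 lower of 458, and chromosome I by 0.29 (0.26 to 0.32, adjusted p = 1.44e-11), with 45 higher and 9 lower of 91. Window medians were 0.46 to 0.80 on XI, 0.32 to 0.76 on XIII and 0.14 to 0.44 on I. Chromosome XII differed by 0.067, with 172 genes higher and 118 lower of 494, and VII by 0.047. CLN3 rose by 0.66 and CCR4 by 0.31, with standard errors of 0.086 to 0.087. The score test called 15 of 16 chromosomes, the lowest of them IV at -0.17, and camera called 7, I, XI and XIII among these.

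The stress list rose in the double mutant, and the lists for ribosomes and the phosphate regulon fell. None of these calls held with an estimated correlation, at adjusted p = 0.0634 for stress, 0.349 for cytosolic ribosomal proteins, 0.300 for ribosome biogenesis and 0.102 for the phosphate regulon. HSP12 went from 11.1 ± 2.86 to 1124 ± 90.6 (6.56). DDR2 (6.27), the desiccation gene SIP18 (YMR175W, 5.48) and the trehalose synthesis gene TSL1 (YML100W, 4.29) rose as well. Falls included PHO5 (-2.78, from 332 ± 8.22 to 47.4 ± 1.63), ANB1 (-2.45), TIR1 (-2.15), ZRT1 (-2.14) and the GTP synthesis gene IMD2 (YHR216W, -2.06). Standard errors were 0.054 to 0.28. In all, 2129 genes were higher and 1902 lower, of which 570 and 73 changed by at least 2-fold. MATa-specific (median -0.43, 2 higher and 3 lower of 8, adjusted p = 0.384) and MATalpha-specific (median 0.49, 2 higher and 1 lower of 4, adjusted p = 0.497) lists were not called.

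Induced stress response genes were all higher (30 higher and 0 lower of 30, median 2.88, adjusted p = 3.77e-18, adjusted p = 0.0634 with an estimated correlation). All genes of the respiratory chain and TCA cycle rose (45 higher and 0 lower of 45, median 0.93, adjusted p = 3.63e-14, adjusted p = 0.0217 with an estimated correlation). CYC7 changed by 2.93, SDH1, on chromosome XI, by 2.0 and COX7, on chromosome XIII, by 1.94. The DNA damage response rose (10 higher and 0 lower of 15, median 0.71, adjusted p = 0.000251, adjusted p = 0.108 with an estimated correlation). RNR3 changed by 1.96 and HUG1 by 2.60. Mitochondrial ribosomal protein genes rose (32 higher and 3 lower of 67, 30 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.00243, adjusted p = 0.363 with an estimated correlation). On chromosome XI, MRP8 changed by 1.46 and RSM22 by 1.39. Proteasome genes were higher (20 higher and 0 lower of 33, median 0.23, adjusted p = 0.00327, adjusted p = 0.529 with an estimated correlation). PRE8, on chromosome XIII, changed by 0.84 and RPT1, on XI, by 0.79. Cytosolic ribosomal protein genes fell (1 higher and 107 lower of 137, 1 and 110 adjusted over the list alone, median -0.62, adjusted p = 4.81e-16, adjusted p = 0.349 with an estimated correlation). RPS26B changed by -1.16. Ribosome biogenesis genes fell (7 higher and 54 lower of 72, 7 and 55 adjusted over the list alone, median -0.36, adjusted p = 5.04e-08, adjusted p = 0.300 with an estimated correlation). Phosphate regulon genes fell (2 higher and 13 lower of 16, median -0.74, adjusted p = 5.42e-05, adjusted p = 0.102 with an estimated correlation). PHO12 changed by -2.18. Haploid-specific genes fell (0 higher and 8 lower of 11, median -0.67, adjusted p = 0.000395, adjusted p = 0.103 with an estimated correlation). The mating endonuclease gene HO changed by -1.89, the G protein gene STE4 by -1.06, GPA1 by -0.98 and the pheromone arrest gene FAR1 by -1.01.

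Chaperones rose in the double mutant (15 higher and 3 lower of 20, median 0.49, adjusted p = 0.00259, adjusted p = 0.179 with an estimated correlation). SSA1 changed by 3.22. Hexose transporters rose (10 higher and 0 lower of 16, median 0.58, adjusted p = 0.00326, adjusted p = 0.123 with an estimated correlation). Cell wall genes rose (14 higher and 5 lower of 22, median 0.80, adjusted p = 0.00387, adjusted p = 0.296 with an estimated correlation). CWP1 changed by 4.11. PAU and COS genes rose (11 higher and 0 lower of 24, median 0.57, adjusted p = 0.0136, adjusted p = 0.0993 with an estimated correlation). Genes of sulfur assimilation and methionine were higher (16 higher and 2 lower of 24, 17 and 2 adjusted over the list alone, median 0.35, adjusted p = 0.0146, adjusted p = 0.0748 with an estimated correlation). Genes near chromosome ends were higher as a list (143 higher and 37 lower of 320, 141 and 37 adjusted over the list alone, median 0.34, adjusted p = 0.00186, adjusted p = 0.0993 with an estimated correlation). The SUMO pathway, including the deleted ULP2, fell (1 higher and 7 lower of 14, median -0.21, adjusted p = 0.0250, adjusted p = 0.247 with an estimated correlation). The SUMO-activating enzyme gene UBA2 changed by -0.53. Histone genes fell (0 higher and 7 lower of 10, median -0.37, adjusted p = 0.0229, adjusted p = 0.507 with an estimated correlation). HTB2 changed by -0.75. The histone call ended without WT replicate 0 (adjusted p = 0.0661, 0.00162 to 0.553 over all alternatives). Early meiosis rose (11 higher and 1 lower of 16, median 0.53, adjusted p = 0.0357, adjusted p = 0.217 with an estimated correlation). That call ended without WT replicate 0 (adjusted p = 0.0528, 1.08e-06 to 0.985 over all alternatives). Quantile normalization turned the median of early meiosis to -0.040 and that of subtelomeric genes to -0.047, and ended the calls of both, of histones, hexose transporters and the PAU and COS families, as a filter of at least 10 FPKM did for early meiosis. Leaving out chromosomes I and XII ended the calls of chaperones and sulfur assimilation, and leaving out VII, XI and XIII too ended also those of histones and the cell wall.

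**Figure D4:**
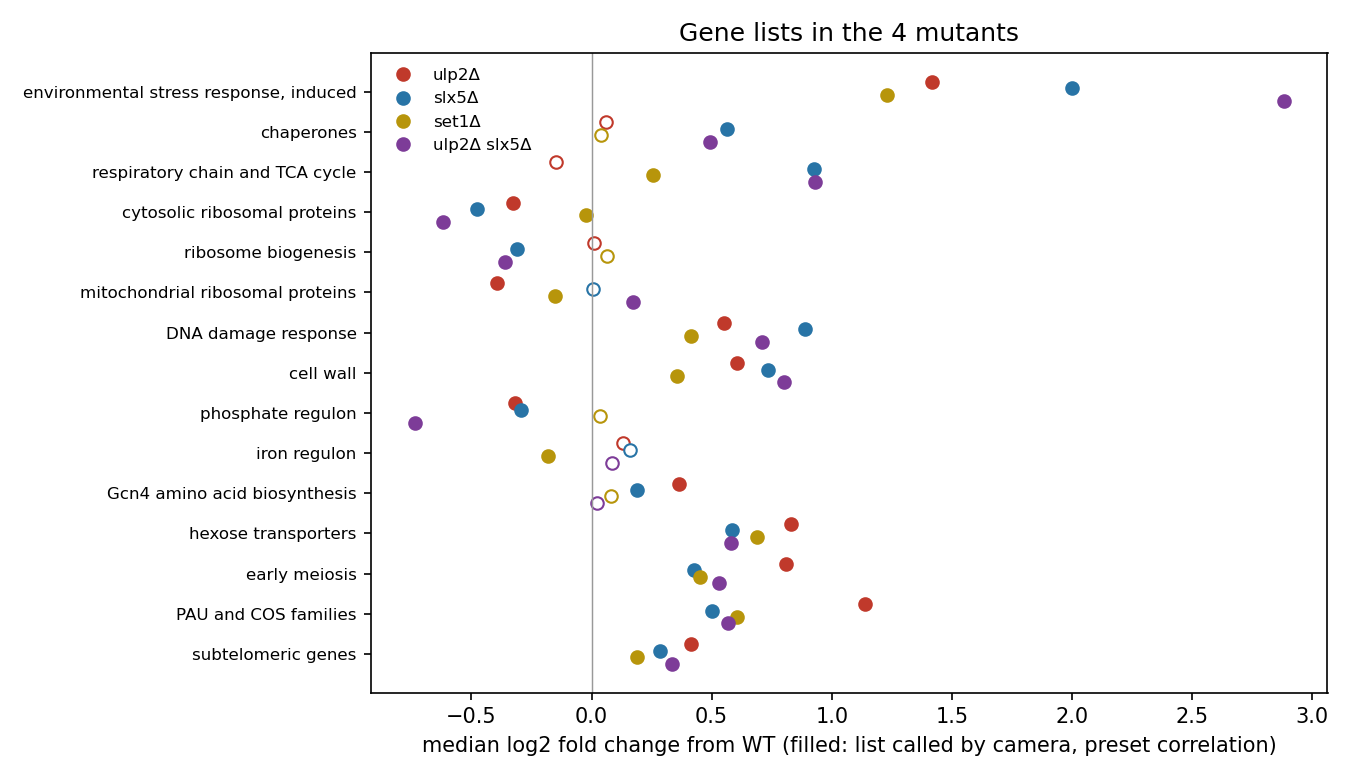
Median log2 fold change from WT of 15 gene lists (x axis) in the 4 mutants, filled where camera with the preset correlation called the list. Induced stress response genes have medians of 1.42 in ulp2, 2.0 in slx5, 1.23 in set1 and 2.88 in the double mutant.

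Deleting SLX5 in cells without ULP2 was addressed by the double mutant against ulp2, which also differ in mating-type expression. Chromosomes I and XII were lower in the double mutant by -0.66 and -0.74, with 3 genes higher and 74 lower of 91 on I and 11 higher and 418 lower of 494 on XII. Chromosomes XI and XIII were higher by 0.76 and 0.42, with 286 higher and 1 lower of 314 on XI and 317 higher and 13 lower of 458 on XIII. The adjusted p was 2.12e-17 for I, 4.05e-22 for XII, 9.72e-23 for XI and 1.93e-18 for XIII. CLN3 changed by -0.48 and CCR4 by -0.34. Outside I and XII, rises included HXK1 (2.55), the glutamate decarboxylase gene GAD1 (YMR250W, 2.37) and the trehalose gene TPS2 (YDR074W, 2.17). FIG1 (-1.98), the agglutinin gene AGA1 (YNR044W, -1.96) and PHO5 (-1.62) fell, and standard errors were 0.054 to 0.13. In all, 1711 genes were higher and 1695 lower, of which 254 and 120 changed by at least 2-fold.

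Relative to ulp2, the respiratory chain and TCA cycle rose (42 higher and 0 lower of 45, 43 and 0 adjusted over the list alone, median 1.09, adjusted p = 4.41e-19, adjusted p = 0.0104 with an estimated correlation). On chromosome XI, SDH1 changed by 2.07 and the malate dehydrogenase gene MDH1 by 2.0. Mitochondrial ribosomal proteins rose (61 higher and 1 lower of 67, 63 and 1 adjusted over the list alone, median 0.60, adjusted p = 5.73e-16, adjusted p = 0.0571 with an estimated correlation). Induced stress genes rose (28 higher and 0 lower of 30, 29 and 0 adjusted over the list alone, median 1.60, adjusted p = 5.89e-15, adjusted p = 0.0787 with an estimated correlation). The proteasome rose (16 higher and 1 lower of 33, median 0.16, adjusted p = 0.00480, adjusted p = 0.540 with an estimated correlation). Chaperones rose (15 higher and 4 lower of 20, median 0.27, adjusted p = 0.00647, adjusted p = 0.225 with an estimated correlation). DNA damage response genes were higher (9 higher and 0 lower of 15, median 0.41, adjusted p = 0.00673, adjusted p = 0.227 with an estimated correlation). RNR2 changed by 1.15. Ribosome biogenesis fell (2 higher and 58 lower of 72, 2 and 59 adjusted over the list alone, median -0.37, adjusted p = 9.60e-11, adjusted p = 0.237 with an estimated correlation). Gcn4 targets fell (3 higher and 31 lower of 37, median -0.47, adjusted p = 4.07e-07, adjusted p = 0.121 with an estimated correlation).

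Cytosolic ribosomal proteins fell relative to ulp2 (6 higher and 60 lower of 137, 6 and 57 adjusted over the list alone, median -0.28, adjusted p = 1.13e-05, adjusted p = 0.639 with an estimated correlation). Mitosis and G2 genes fell (0 higher and 9 lower of 14, 0 and 11 adjusted over the list alone, median -0.22, adjusted p = 0.00292, adjusted p = 0.179 with an estimated correlation). The haploid-specific list fell (1 higher and 7 lower of 11, median -0.53, adjusted p = 0.00488, adjusted p = 0.182 with an estimated correlation). The phosphate regulon fell (2 higher and 10 lower of 16, median -0.42, adjusted p = 0.00557, adjusted p = 0.237 with an estimated correlation). MATalpha-specific genes were lower (0 higher and 4 lower of 4, median -5.84, adjusted p = 2.17e-06, adjusted p = 0.0104 with an estimated correlation). MATa-specific genes were higher (7 higher and 1 lower of 8, median 2.50, adjusted p = 0.000419, adjusted p = 0.111 with an estimated correlation). Early meiosis fell (1 higher and 8 lower of 16, 1 and 9 adjusted over the list alone, median -0.32, adjusted p = 0.0320, adjusted p = 0.209 with an estimated correlation). Its call ended without ulp2 replicate 2 (adjusted p = 0.0559). The range over all alternatives was 4.06e-05 to 0.318. Quantile normalization ended the calls of early meiosis and cytosolic ribosomal proteins, and a filter of at least 10 FPKM that of early meiosis.

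Deleting ULP2 in cells without SLX5 was addressed by the double mutant against slx5, again with different mating-type expression and with MET17 near 0 in slx5 alone. Chromosome XI was higher by 0.53, with 272 genes higher and 2 lower of 314, and XIII by 0.52, with 374 higher and 4 lower of 458. Chromosome I was higher by 0.24, with 38 higher and 0 lower of 91, XII by 0.046, and VII was lower by -0.19, with 22 higher and 181 lower of 531. The adjusted p was 9.96e-21 for XI, 7.26e-20 for XIII, 1.27e-10 for I and 1.83e-12 for VII. CLN3 rose by 0.60 and CCR4 by 0.49. SIP18 (3.79), the desiccation gene GRE1 (YPL223C, 2.28) and the aldehyde dehydrogenase gene ALD3 (YMR169C, 1.82) rose. AGA1 (-1.89), HUG1 (-1.88) and FIG1 (-1.71) fell, and standard errors were 0.068 to 0.28. In all, 1118 genes were higher and 870 lower, of which 66 and 28 changed by at least 2-fold.

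Relative to slx5, induced stress genes rose (19 higher and 0 lower of 30, 19 and 1 adjusted over the list alone, median 0.54, adjusted p = 3.63e-07, adjusted p = 0.225 with an estimated correlation). Mitochondrial ribosomal proteins were higher (23 higher and 0 lower of 67, 24 and 0 adjusted over the list alone, median 0.16, adjusted p = 1.11e-05, adjusted p = 0.209 with an estimated correlation). Gcn4 targets were lower (4 higher and 26 lower of 37, 5 and 28 adjusted over the list alone, median -0.28, adjusted p = 3.63e-07, adjusted p = 0.119 with an estimated correlation). Phosphate regulon genes were lower (1 higher and 10 lower of 16, median -0.51, adjusted p = 2.17e-06, adjusted p = 0.0634 with an estimated correlation). SPL2 changed by -1.36. Haploid-specific genes were lower (1 higher and 7 lower of 11, median -0.36, adjusted p = 6.93e-05, adjusted p = 0.0754 with an estimated correlation). Sulfur assimilation and methionine fell (2 higher and 10 lower of 24, median -0.18, adjusted p = 0.00870, adjusted p = 0.0634 with an estimated correlation). The DNA damage response fell (3 higher and 6 lower of 15, median -0.30, adjusted p = 0.0243, adjusted p = 0.295 with an estimated correlation). RNR4 changed by -0.80. Ergosterol synthesis fell (3 higher and 12 lower of 24, median -0.20, adjusted p = 0.00673, adjusted p = 0.382 with an estimated correlation). ERG26 changed by -0.78 and ERG3 by -0.57.

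Cytosolic ribosomal proteins were lower than in slx5 by camera (7 higher and 16 lower of 137, 6 and 11 adjusted over the list alone, median -0.15, adjusted p = 0.00448, adjusted p = 0.746 with an estimated correlation). Proteasome genes were also lower by camera (3 higher and 9 lower of 33, median -0.10, adjusted p = 0.0275, adjusted p = 0.639 with an estimated correlation). Neither list was called by fry or after quantile normalization. MATa-specific genes rose (7 higher and 1 lower of 8, median 3.52, adjusted p = 1.58e-07, adjusted p = 0.0555 with an estimated correlation). MATalpha-specific genes fell (0 higher and 4 lower of 4, median -6.21, adjusted p = 1.09e-10, adjusted p = 0.00635 with an estimated correlation). Leaving out chromosomes I, VII, XI, XII and XIII ended the call of the DNA damage response relative to slx5.

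The interaction asked whether the double mutant departed from the sum of the ulp2 and slx5 effects on the log2 scale. Chromosomes XII and I fell short of the sum by -0.76 and -0.72 and chromosomes XI and XIII exceeded it by 0.62 and 0.45 (adjusted p = 5.87e-20, 1.07e-15, 1.32e-19 and 1.15e-16). Of 6474 genes, 1293 exceeded the sum and 1413 fell short of it, by at least 2-fold for 111 and 401. HSP12 (-4.56), HSP26 (-4.01) and PIR3 (-3.32) fell short, as did FIG1 (-5.24), PRM6 (YML047C, -4.58) and AGA1 (-3.68), known as induced by pheromone. TIR1 (2.33), the peptide transporter gene PTR2 (YKR093W, 2.33) and RPL8A (2.12) exceeded the sum. Standard errors over these genes were 0.077 to 0.21. For CLN3 the departure was -0.54, and for CCR4 it was -0.16 and not called. Since only the singles had the mating-type expression of alpha cells, the sum counts that difference from WT 2 times and the double mutant does not. LYS2 was near 0 in WT alone of these 4 strains, and MET17, a sulfur gene, in slx5 alone, so the departures, that of the sulfur list included, are not those of ULP2 and SLX5 alone.

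Mitochondrial ribosomal proteins exceeded the sum (58 higher and 1 lower of 67, 59 and 1 adjusted over the list alone, median 0.55, adjusted p = 2.87e-14, adjusted p = 0.0586 with an estimated correlation). MATa-specific genes exceeded it (7 higher and 1 lower of 8, median 6.85, adjusted p = 4.66e-07, adjusted p = 0.0586 with an estimated correlation). Cytosolic ribosomal proteins exceeded it (32 higher and 10 lower of 137, 29 and 8 adjusted over the list alone, median 0.21, adjusted p = 0.00245, adjusted p = 0.723 with an estimated correlation). Their call ended, beside fry, without WT replicate 0 (adjusted p = 0.0709). The adjusted p over all alternatives was 2.79e-06 to 0.723. Gcn4 targets fell short of the sum (1 higher and 32 lower of 37, 1 and 33 adjusted over the list alone, median -0.57, adjusted p = 4.31e-11, adjusted p = 0.0634 with an estimated correlation). MATalpha-specific genes fell short (0 higher and 4 lower of 4, median -12.44, adjusted p = 5.89e-09, adjusted p = 0.00635 with an estimated correlation). Sulfur assimilation and methionine fell short (0 higher and 15 lower of 24, 0 and 16 adjusted over the list alone, median -0.66, adjusted p = 2.26e-06, adjusted p = 0.0104 with an estimated correlation). Early meiosis fell short (0 higher and 10 lower of 16, median -0.63, adjusted p = 0.000300, adjusted p = 0.0597 with an estimated correlation). Subtelomeric genes fell short (34 higher and 111 lower of 320, median -0.37, adjusted p = 0.000395, adjusted p = 0.0686 with an estimated correlation).

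DNA damage response genes fell short of the sum (1 higher and 10 lower of 15, median -0.68, adjusted p = 0.000803, adjusted p = 0.132 with an estimated correlation). The cell wall list fell short (5 higher and 16 lower of 22, median -0.79, adjusted p = 0.00203, adjusted p = 0.272 with an estimated correlation). Induced stress genes fell short (4 higher and 15 lower of 30, 5 and 15 adjusted over the list alone, median -0.44, adjusted p = 0.00252, adjusted p = 0.476 with an estimated correlation). PAU and COS genes fell short (2 higher and 10 lower of 24, median -0.69, adjusted p = 0.00307, adjusted p = 0.0634 with an estimated correlation). Hexose transporters fell short (1 higher and 8 lower of 16, median -0.70, adjusted p = 0.00312, adjusted p = 0.122 with an estimated correlation). Chaperones also fell short (5 higher and 10 lower of 20, 6 and 11 adjusted over the list alone, median -0.22, adjusted p = 0.0497, adjusted p = 0.365 with an estimated correlation). Their call ended without WT replicate 1 (adjusted p = 0.0514), without ulp2 replicate 0 (adjusted p = 0.0621), without ulp2 replicate 1 (adjusted p = 0.0534), without ulp2 replicate 2 (adjusted p = 0.0502), without slx5 replicate 0 (adjusted p = 0.0515), without slx5 replicate 1 (adjusted p = 0.0520), without slx5 replicate 2 (adjusted p = 0.0557), without double mutant replicate 0 (adjusted p = 0.0586) and without double mutant replicate 2 (adjusted p = 0.0519). The adjusted p over all alternatives was 1.18e-05 to 0.446. Quantile normalization ended the calls of early meiosis, cytosolic ribosomal proteins, hexose transporters and subtelomeric genes, and leaving out chromosomes I and XII, or a pseudocount of 0.1, that of chaperones. A filter of at least 10 FPKM ended that of hexose transporters.

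Whether mutants changed the same genes was tested by overlap of the calls against WT. In ulp2 and slx5, 1032 genes were higher in both (461 if independent) and 948 lower (434), while 298 changed in opposite directions. For ulp2 and the double mutant the counts were 1156 higher (592 if independent) and 1077 lower (507). For slx5 and the double mutant they were 1365 higher (546) and 1298 lower (478), with 89 opposite. In ulp2 and set1, 862 were higher (397) and 576 lower (262), in slx5 and set1 972 (366) and 537 (247), and in set1 and the double mutant 1038 (470) and 591 (289). In all 4 mutants 658 genes were higher and 346 lower, of which 113 and 3 by at least 2-fold in each. The 3 WT libraries, control to all 4 mutants, add to the overlap. LYS2 (all but set1) and mating-type expression (ulp2, slx5, set1) differed from WT too and may add. Across genes, which are not independent replicates, log2 changes of the 6 pairs of mutants correlated by 0.51 to 0.76, where 50 simulations with shared controls and no effects gave 0.49 to 0.51. The lowest was that of set1 and the double mutant, at 0.51 against 0.50 simulated, with a covariance of 0.22 against 0.037.

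Glycolysis and fermentation (median -0.20, 4 higher and 9 lower of 17, adjusted p = 0.0723 in ulp2) and chromosome segregation (median -0.076, 4 higher and 6 lower of 25, adjusted p = 0.384 in ulp2, 4 and 5 adjusted over the list alone) were called in none of the 7 comparisons. Histones (median -0.17, 1 higher and 3 lower of 10, adjusted p = 0.122), ergosterol synthesis (median -0.077, 5 higher and 10 lower of 24, adjusted p = 0.192), the respiratory chain and TCA cycle (median -0.15, 6 higher and 14 lower of 45, adjusted p = 0.0979) and the proteasome (median 0.030, 6 higher and 2 lower of 33, adjusted p = 0.568, 6 and 0 adjusted over the list alone) were not called in ulp2. Neither were mitosis and G2 (median 0.085, 5 higher and 3 lower of 14, adjusted p = 0.331) and haploid-specific genes (median -0.10, 2 higher and 4 lower of 11, adjusted p = 0.225). Of the 6 genes listed as silent mating loci and MAT, HMRA1 alone was tested, with the values given above, and MATALPHA1, HMLALPHA1, HMLALPHA2 and HMRA2 were listed at 0 in all libraries. No Ty element was matched, so that list had 0 members. Among lists not called, median, mean and test differed in sign also for Gcn4 targets, glycolysis and chromosome segregation in the double mutant against WT.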

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

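The results here were set apart because the effect of a deletion differed between backgrounds, as tested by the interaction of the ulp2 and slx5 deletions. Tests of a gain or doubling of part of a chromosome, of the kind of genes as the whole cause of the shift of I, and the comparison with slx5 and set1, were chosen only after the results were seen. No test for a library far from its group was run.

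The ulp2 effect differed between cells with and without SLX5 in 2706 genes. In a fit on these 4 groups, the real split of the 12 libraries gave 2779 genes. Others of 100 drawn, of the same group sizes, gave at most 400. They mix strains and cannot test the interaction alone. For the comparisons of 3 against 3, the 10 splits of 6 libraries are too few to decide. The real split called 3004 genes for ulp2 against WT (highest other 2), 3031 for slx5 (2), 1465 for set1 (3), 3767 for the double mutant (2), 3423 for the double mutant against ulp2 (4) and 2551 against slx5 (3). The strains also differed in mating-type expression, LYS2 and MET17, so these numbers are not those of the named deletions alone.

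Interaction scores of 9 chromosomes passed the test, at -0.72 for I, -0.12 for VI, -0.11 for VII, 0.095 for IX, -0.048 for X, 0.62 for XI, -0.76 for XII, 0.45 for XIII and 0.042 for XVI. Among genes, the interaction was 2.33 for TIR1, 2.33 for PTR2, 2.12 for RPL8A, 1.85 for GYP8, 1.71 for TPO4, 1.70 for TPS2, 1.68 for HEM13 and 1.57 for PHD1. It was -5.24 for FIG1, -4.76 for MNC1, -4.58 for PRM6, -4.56 for HSP12, -4.01 for HSP26, -3.68 for AGA1, -3.66 for DDR2 and -3.32 for PIR3. List medians of the interaction were 6.85 for MATa-specific and -12.44 for MATalpha-specific genes, -0.63 for early meiosis, 0.21 for cytosolic and 0.55 for mitochondrial ribosomal proteins, -0.44 for induced stress genes, -0.22 for chaperones, -0.66 for sulfur assimilation and -0.57 for Gcn4 targets. They were -0.70 for hexose transporters, -0.68 for the DNA damage response, -0.79 for the cell wall, -0.69 for the PAU and COS families and -0.37 for subtelomeric genes.

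Chromosome shifts differed from ulp2, with VII higher in slx5 and I, XI and XIII in the double mutant. Genes from other chromosomes were drawn 10000 times, matched on WT level and on the change in set1. Shifts were at most 0.034, -0.011 and 0.044 for VII, XI and XIII, and 0.18 for I, against a shift of 0.26. These features were argued against, for I as the whole cause only. Other kinds of genes were not matched and stay open. A gain of part of the chromosome was argued against for XI and XIII, whose lowest windows were 0.46 and 0.32. For VII and I, whose lowest windows of 0.10 and 0.14 lay within the range of other chromosomes, a doubling of part of the chromosome in all cells was argued against by highest windows of 0.37 and 0.44, and a smaller gain of part of it stays open. A gain in part of the cells may give shifts of this size as well and was not tested, as the biological explanation of an extra chromosome was not.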

How the results depend on the processing

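Camera on the genes of a chromosome, leaving out 5 chromosomes, protein-coding genes alone, and gene counts against slx5 and set1 were alternatives chosen after the data were seen. A change of sign counts where the reported or the alternative value is called, and for lists it is that of the test's direction, not of the median. Outside the leave-one-out settings, chromosome scores kept direction and call in 1224 cases, lost the call in 89, gained it in 30 and reversed in 17. For lists the counts were 2195, 166, 66 and 2, and for named genes 6185, 43, 0 and 5. Chromosomes I and XII in ulp2, VII in slx5 and I, XI and XIII in the double mutant kept direction and call throughout. Causes were not tested, except where stated. Depth is unknown, so what it limits was not measured.

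With a pseudocount of 0.1, XII in set1 was 0.017 and called, and with 5, I in slx5 was 0.023 and not called. With at least 10 FPKM, VI in ulp2 reversed to -0.049 from 0.02, I was not called in slx5 (0.019) and set1 (0.032), and XII in set1 was called (0.022). Quantile normalization moved the median of all genes in the double mutant from 0.025 to -0.11 and the share of calls that were higher from 51.0 to 39.2% in ulp2, 50.5 to 40.5% in slx5, 59.3 to 48.6% in set1 and 52.8 to 39.9% in the double mutant. Rescaling outside I and XII moved that share the other way in ulp2, to 59.3%, and lowered it from 50.2 to 43.9% in the double mutant against ulp2 and from 47.8 to 41.5% in the interaction. Quantile normalization reversed EFB1 in slx5 (0.11 from -0.35) and the double mutant (0.26 from -0.22), CDC19 there (0.036 from -0.33) and early meiosis (-0.040 from 0.53), while for subtelomeric genes in the double mutant the median turned (-0.047) and the test's direction did not. RPL41A, top-ranked in every library and so set to one value, went to 0 from -1.36 against WT and from -1.60 against slx5. Chromosome I in slx5 was then 0.00476 and not called.

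With means over genes, III (-0.040) and IX (-0.049) in ulp2, II in slx5 (0.00813), II (0.00544) and V (0.00712) in the double mutant against ulp2, and III (0.058) and V (0.055) in the interaction reversed. I in slx5 (0.021) was not called, XII in set1 (0.041) was, and 11 other chromosomes passed in the interaction instead of 7. Centred on WT, III in the double mutant (-0.00243) and against ulp2 (-0.035), and XV (-0.034) and XVI (-0.00412) in the interaction reversed, and I in slx5 (0.034) was not called. Without chromosome ends, VI in the double mutant reversed (-0.052), I in slx5 (0.029) was not called and XII in set1 (0.018) was. Against slx5 and set1, III (-0.027) and VI (-0.086) in ulp2 reversed.

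Beside camera, the median change of the chromosome's genes, less that of the other chromosomes, took the opposite sign to the score for III in the double mutant (-0.023) and XVI against ulp2 (0.000854), while camera kept the direction of both scores without calling them. I in slx5 (0.031) and set1 (0.044), XII in slx5 (0.027), in the double mutant (0.062) and against slx5 (0.067) were not called. Camera called 1 other chromosome in ulp2, 3 in slx5, 0 in set1, 6 in the double mutant, 3 against ulp2 and 2 in the interaction, where scores called 11, 13, 6, 13, 12 and 7.

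A 2-fold limit left 543 genes in ulp2, 464 in slx5, 260 in set1, 643 in the double mutant, 374 against ulp2, 94 against slx5 and 512 in the interaction. With 5 chromosomes left out, and so fewer genes tested, 2236 were called in ulp2, 1582 in set1, 1954 against ulp2, 823 against slx5 and 1342 in the interaction. A fit on set1 and WT alone called 1465. The replicate block gave 3527, 3310, 2404, 4016, 3406, 1976 and 2688 genes in the 7 comparisons.

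With an estimated correlation, lists called fell to 2, 3, 2, 1, 2, 1 and 2 from 17, 18, 20, 18, 15, 12 and 14, in the order given for the 2-fold limit. By fry, 17, 18, 19, 18, 15, 10 and 13 of the called lists passed, and hexose transporters against ulp2 were called higher, where camera pointed lower without a call (median -0.21).

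Leaving out a library gave 3178 to 3412 genes in ulp2, 2905 to 3124 in slx5, 2081 to 2235 in set1, 3678 to 3833 in the double mutant, 3020 to 3161 against ulp2, 1584 to 1615 against slx5 and 2418 to 2694 in the interaction. Scores ran from 0.94 to 0.98 for I and 0.79 to 0.81 for XII in ulp2, 0.028 to 0.070 for I and 0.012 to 0.027 for XII in slx5, 0.064 to 0.097 for I and 0.00657 to 0.022 for XII in set1, and 5 to 10 other chromosomes passed in set1, with 10 without set1 replicate 2.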

Other observations

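FIG1, PRM6, AGA1 and FUS1, each known as induced by pheromone, were named by the rule in 1 or more comparisons, and their group was not tested as a list. In ulp2, slx5, set1 and the double mutant against WT, FIG1 had log2 values of 3.53, 3.26, 3.01 and 1.55, PRM6 2.81, 2.71, 2.38 and 0.94, AGA1 1.8, 1.72, 1.31 and -0.17, and FUS1 0.94, 1.2, 0.74 and -0.35. TIR1, ANB1, AAC3 and HEM13, each known as repressed in air, were not tested as a list either. In the same order, TIR1 had -2.42, -2.06, 0.11 and -2.15, ANB1 -0.94, -2.39, -1.01 and -2.45, the ADP/ATP carrier gene AAC3 -0.69, -1.81, -0.38 and -2.07, and HEM13 -1.77, -1.53, -0.47 and -1.62. Of these values, that of AGA1 in the double mutant and that of TIR1 in set1 did not pass the test.

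The tests of cells mixed into ulp2, of the comparison of ulp2 with slx5 and set1, and of the mating type of the double mutant were chosen only after the results were seen. In ulp2, 6 of 7 MATa-specific genes stood above slx5, by 1.49 for MFA1, 1.71 for MFA2, 1.13 for STE2, 0.93 for BAR1, 0.80 for AGA2 and 0.67 for ASG7, with STE6 not called at 0.080, and against set1 these were 3.01, 1.67, 1.96, 1.77, 3.77, 1.31 and 0.42. In slx5 all but MFA2 stood above set1 as well, by 0.34 for STE6 to 2.97 for AGA2. Admixture of MATa cells was argued against, since HMRA1 reached at most 0.206% of its WT level in a ulp2 library while the 7 genes had a median of 4.30 to 6.49% less the slx5 level, and of 6.19 to 9.27% less the set1 level. Scaling was argued against, with at least 6 of the 7 genes above slx5 and set1 together, and 5 above slx5 alone, under each scaling, as was a place on chromosomes I and XII, with 0 of the 7 there. The ulp2 deletion, as the difference the design names, stays open and was not tested.

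The double mutant libraries, labelled MATalpha, expressed HMRA1 and little MF(ALPHA)1 or STE3, while MATa-specific genes stood at 47.9 (MFA2) to 122% (STE6) of their WT mean. A swap with WT libraries was argued against by ULP2 and SLX5, which reached at most 0.280% of their lowest WT value there. A mixture of MATa with haploid MATalpha cells was argued against by MF(ALPHA)1 and STE3, which, less their WT level, reached at most 1.44% of their level in ulp2, slx5 and set1. Cells carrying both mating types mixed in stay open, since 4 of the 7 MATa-specific genes (MFA1, MFA2, STE2 and BAR1) lay below every WT library while STE6, AGA2 and ASG7 did not, and haploid-specific genes fell (median -0.67). STE6 lies on chromosome XI, which was higher by 0.67 in the double mutant. Its level was not adjusted for that shift, so it is weak evidence of a gene kept at the WT level. A strain of another mating type than its label stays open as well, with the lowest HMRA1 value at 99.9% of the lowest WT value. Why those 4 genes were lower was not tested.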
